A study of Haemaphysalis flava with 2 samples.

How the data were processed

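Polyadenylated RNA from the midgut of the hard tick Haemaphysalis flava was sequenced at 2 states of blood feeding, fully engorged (FE) and partially engorged (PE), with 1 library per state. Per the labels, 60 midguts were dissected, 30 per state. How many of them went into each library is not given in the sources used here. RNA was extracted with Trizol and libraries followed the TruSeq RNA guide, per the labels' protocols. CASAVA 1.8 is named in the submitters' processing notes. The assembler, the aligner and the counting tool are not given in the sources used here. No reference genome was used, and features are the unigenes (assembled transcripts or transcript fragments) of the deposited tables, under the names given there.

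The authors deposited read counts per unigene, which are whole numbers with no normalization, per the file headers. The authors deposited RPKM values (reads scaled to unigene length in kilobases and to library size) beside them. Dividing the counts by the RPKM values and the unigene lengths gave 1 library total for all unigenes of a library, 41432770 reads for FE and 50397332 for PE. The listed counts summed to 86.8% and 87.0% of these totals. The expression table held 65535 unigenes and a header, 65536 lines in all, and the annotation tables named unigenes beyond it (3321 of 23395 with a Nr hit), so it holds part of each library. Counting intervals therefore used the implied totals. Unigenes outside the table were not analysed here.

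A second table held the authors' comparison. In it the authors gave the ratio (fold change) of PE over FE RPKM, with values of 0 replaced by 0.00001, per the file headers and the values. The authors also deposited a p-value and a false discovery rate per unigene, and the test behind them is not given in the sources used here. Its direction column, as other text in the deposited tables, marked every unigene UP (ratio above 1, higher in PE) or DOWN, whatever the false discovery rate. Protein descriptions from Nr (20074 unigenes of the table) and UniProt (22868), KOG classes (12697) and GO terms (14930) were deposited by the authors. The search tools and cut-offs behind them are not given in the sources used here.

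With 1 library per state there was no spread between replicates, so no test between the states was run and no p-value was computed. A unigene was called higher or lower in the FE library by a rule of size. The log2 of (FE RPKM + 1)/(PE RPKM + 1) had to be at least 1 or at most -1, which understates the ratio of low unigenes. The 95% exact (Clopper-Pearson, conditional binomial) interval of the ratio of counts had to exclude 1. Only unigenes with at least 1 RPKM in one of the libraries entered. Intervals and floors cover counting error only, and PCR copies were not removed by molecular identifiers. Ratios printed as folds are RPKM ratios without the added 1, with this interval. Where 1 library had 0 reads the fold is a lower bound against a floor of 3 reads in that library. The floor of 3 reads was 0.0724 RPKM per kilobase of unigene in FE and 0.0595 in PE.

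Gene lists were 28 fixed word patterns on the Nr description, or the UniProt description where Nr gave none. For each list the median log2 ratio minus the median of all unigenes was taken (the relative median), with an order-statistic 95% interval over the members. Its percentile among 10000 random lists of the same size, matched on mean level in 20 bins, describes these 2 libraries. A list was called apart when it lay outside the central 95% of the random lists. KOG classes of at least 20 unigenes, by the letters of the best-scoring hit, were treated in the same way. The patterns, the rule of size, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text draws on unigenes with an informative description: the 10 with the highest mean level, the 8 highest and 8 lowest ratios among those of at least 10 RPKM in a library, and, for each list called apart and 6 focal lists, the most abundant member and those with the highest and lowest ratio at that level. The first rankings, but not those within lists, kept for each description only the unigene with the highest mean level, which leaves out more extreme ones that share it. Unigenes said to be further examples were chosen after their values were seen.

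The rule was tested on simulated reads drawn from the real means and library totals, with 200 unigenes changed among 41077 that passed the filter. The changed unigenes were drawn only from those with a mean of at least 2 RPKM. In that simulated comparison of FE with PE the rule called 94 of 100 unigenes changed 3-fold, 100 of 100 changed 6-fold, and 2 of 40877 unchanged ones. Recovery of changes in scarcer unigenes, where the pseudocount weighs more, was not tested. Among 200 random lists of 30 unchanged or changed unigenes, 11 lay outside the central 95%. These lists were drawn at random from the same simulated unigenes, so a small share outside was fixed in advance. That count therefore says nothing about lists of related unigenes or fragments. The simulation holds counting noise only, not variation between ticks.

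Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, ratios centred on their median over unigenes of at least 10 RPKM in both libraries, a TMM factor (trimming 30% of ratios and 5% of levels), 1 unigene per best-hit protein, a 4-fold rule, no counting interval, CPM values with no length term, random lists matched also on length, and descriptions from Nr or UniProt alone. Leaving out descriptions that match a pattern but not its meaning was added after seeing the data. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures used matplotlib 3.10.9.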

Results

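The transcriptome of the tick midgut, the organ that stores and digests the blood meal, was compared between fully engorged (FE) and partially engorged (PE) Haemaphysalis flava. Each state was represented by 1 library, so no difference below has a replicate check and none can be set against variation between ticks. The listed reads came to 35944321 in the FE library and 43831353 in the PE library, over 65535 unigenes with a median length of 544 nucleotides. Reads were found for 64363 unigenes in FE and 63669 in PE, and 44982 unigenes reached 1 RPKM in a library. A protein description was attached to 18815 of these.

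The comparison of FE with PE asked which midgut transcripts differ between the end of the blood meal and an earlier point of it. In the FE library a defensin and most unigenes of immunoglobulin-binding proteins, histones, fatty acid elongases and zinc finger proteins stood higher. The abundant trypsin-like proteases, an abundant Kunitz inhibitor, most of the abundant hemelipoglycoproteins and 86 of 227 cytochrome P450s stood lower. By the 2-fold rule 11551 unigenes were higher in FE and 4992 were lower, while 28439 were neither. Differences of 16-fold or more on the log2(RPKM + 1) scale were about even, 167 higher and 158 lower. The split depended on scaling: 69.8% of the called unigenes were higher in FE with the authors' RPKM, 61.6% after centring on well expressed unigenes (9655 higher, 6025 lower) and 53.6% with a TMM factor (8217 higher, 7125 lower). The median log2 ratio of all unigenes was 0.36 and the TMM factor was 0.39 on the log2 scale, so lists are given relative to the median.

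**Figure D1:**
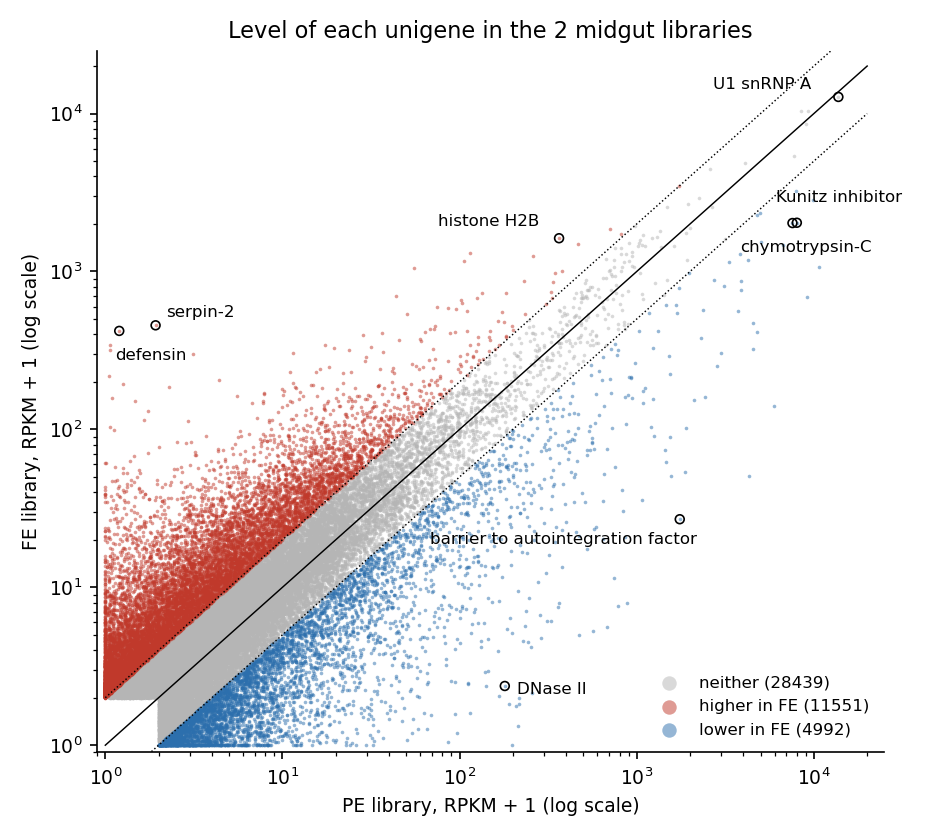
RPKM + 1 of each of 44982 unigenes in the PE library (x axis) and the FE library (y axis), both on log scales. Red points are the 11551 unigenes higher in FE and blue points the 4992 lower in FE, the solid line marks equal values, dotted lines mark 2-fold, and circles mark named unigenes such as defensin (419.5 RPKM in FE, 0.198 in PE).

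Trypsin-like serine proteases, which cut proteins outside the cell at neutral or alkaline pH, were lower in FE as a list. Of 32 members 19 were lower, 10 were higher and 3 were neither, with a relative median of -1.69 (95% interval -3.14 to 0.66) at percentile 0 of the random lists. All 9 members with a mean of at least 100 RPKM were lower. The most abundant, a chymotrypsin-C precursor (Contig291), read 2026 RPKM in FE and 7573 in PE, 3.74-fold higher in PE (95% counting interval 3.71 to 3.77). Midgut serine proteinase-2 (First_Contig2802) had 3.16 RPKM in FE and 251 in PE, 79.3-fold higher in PE (67.8 to 93.5). In the other direction a stubble-like serine proteinase (Contig3023) was 5.83-fold higher in FE (5.51 to 6.17), at 98.6 against 16.9 RPKM. The interval of the median includes 0, and members went both ways.

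Cathepsins, legumain and related enzymes digest hemoglobin inside tick midgut cells at acid pH. This list of 41 had a relative median of -0.59 (percentile 0.48), with 10 members higher, 8 lower and 23 neither (7 higher and 10 lower with a TMM factor). Cathepsin B (Contig5046), its most abundant member, had 569 RPKM in FE and 829 in PE. A legumain (Contig3807) was 4.16-fold higher in PE (4.0 to 4.33), and an aspartic protease described in UniProt as cathepsin D (Contig10076) was 58.5-fold higher in FE (45.8 to 75.8). The list was inside the random range without the filter (-0.13) and with 1 unigene per protein (-0.44). Its pattern did not match the 2 longipain unigenes described below, which were both higher in FE. Metallopeptidases (52 members, 24 higher, 9 lower) had a relative median of 0.45 (percentile 99.5), which was -0.15 over the 19 members left by a filter at 5 RPKM. The extremes were a nas-15-like metalloproteinase (Contig7888), 26.9-fold higher in FE (20.1 to 36.9), and a metalloproteinase (Contig11233) 11.0-fold higher in PE (9.79 to 12.3). The most abundant, a YME1 homolog of mitochondria (Contig7836), had 19.2 and 34.9 RPKM.

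Protease inhibitors went both ways. Of 86 members 34 were higher in FE, 29 lower and 23 neither (30 higher and 35 lower with a TMM factor), and the relative median of -0.26 lay inside the random range (percentile 3.52). Among the 15 with a mean of at least 100 RPKM, 11 were lower and 3 higher. The pattern did not match the neutrophil elastase inhibitor Contig58, called neither at 4882 RPKM in FE and 4059 in PE. These counts leave it out. A Kunitz inhibitor (Contig14665) was among the most abundant transcripts of the PE library, at 8015 RPKM against 2035 in FE, 3.94-fold higher in PE (3.90 to 3.98), and a trypsin inhibitor precursor (Contig41925) was 103-fold higher in PE (57.5 to 207). The serpin-2 precursor (Contig1645), of a family that blocks serine proteases, had 455 RPKM in FE and 0.922 in PE, 494-fold higher in FE (339 to 749). As further examples, the 2 most abundant cystatin-2 unigenes, inhibitors of cysteine proteases, went opposite ways: Contig3042 was 4.16-fold higher in PE (4.07 to 4.25) and Contig499 was 2.56-fold higher in FE (2.49 to 2.63). Over the whole family serpins had 13 of 40 higher and 18 lower (12 and 21 with a TMM factor), among them Contig13297, 6.81-fold higher in PE (6.45 to 7.21), and cystatins had 7 of 10 higher and 1 lower (5 and 2). With a filter at 5 RPKM the inhibitor list fell outside the random range on the lower side (-1.11), and without a filter its median was above 0 and inside the range (0.16, percentile 86.1).

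**Figure D2:**
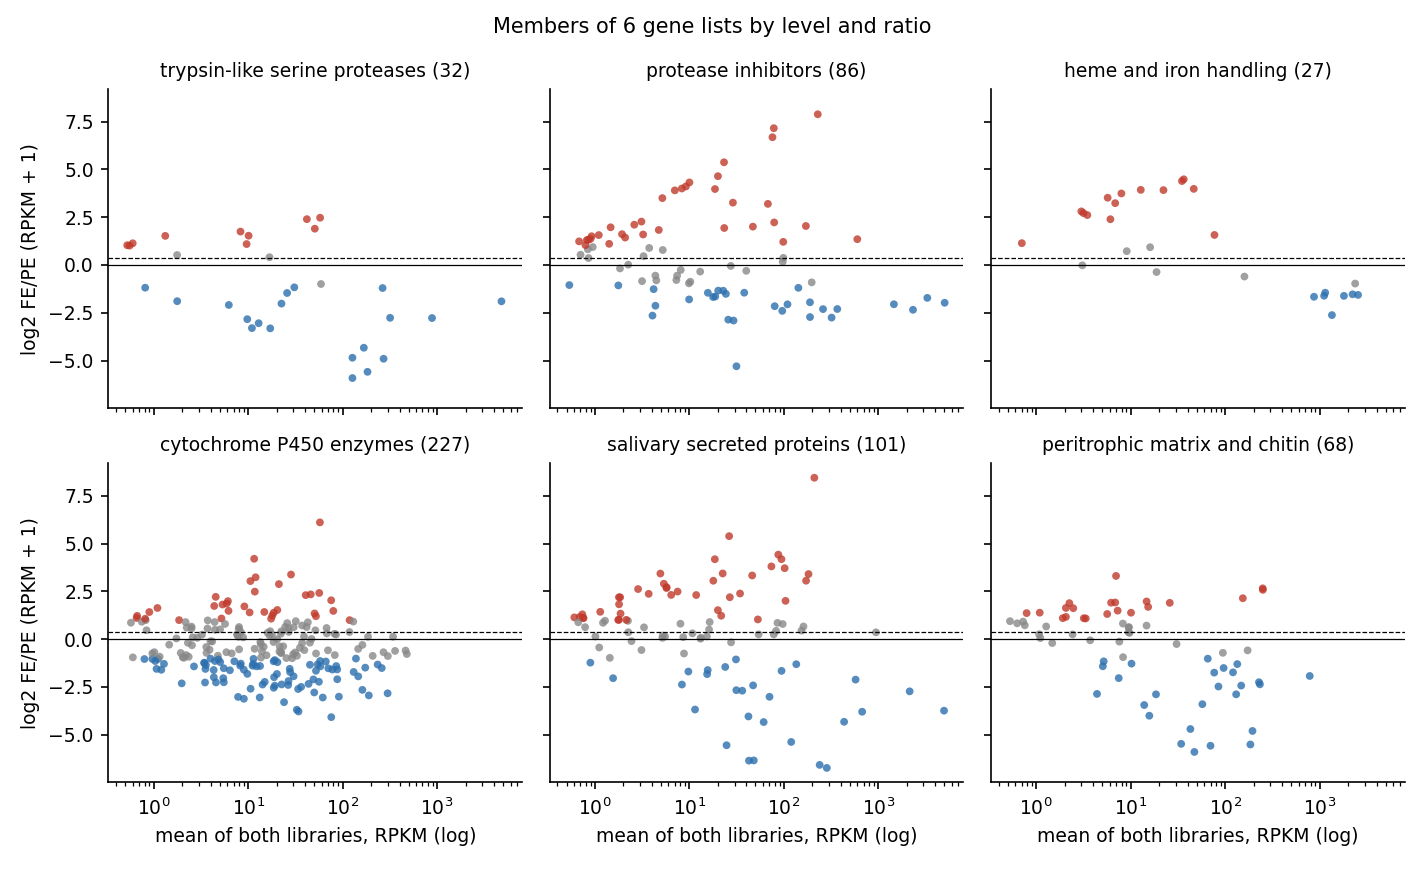
Each point is a unigene of 1 of 6 gene lists, with the mean RPKM of both libraries on a log x axis and the log2 FE/PE ratio of RPKM + 1 on the y axis. Red points are at least 2-fold higher in FE, blue points at least 2-fold lower, the solid line marks 0 and the dashed line the median of all unigenes (0.36). All 9 trypsin-like proteases above 100 RPKM lie below -1.

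Heme and iron carriers split by sequence. Hemelipoglycoproteins carry heme and lipid in tick hemolymph, and the 8 unigenes of this kind whose UniProt hit was vitellogenin-1 or putative vitellogenin-1 held the largest values of the list. Of these, 7 were lower in FE. Contig1058 had 1286 RPKM in FE and 3808 in PE, 2.96-fold higher in PE (2.94 to 2.98), Contig758 was 6.17-fold higher in PE (6.03 to 6.32), and Contig757 had 1601 and 3142 RPKM, just short of the rule. Of 8 whose UniProt hit was vitellogenin-2 in either spelling, 7 were higher in FE, at lower levels, from 1.35 to 88.2 RPKM in FE against 0.0614 to 4.63 in PE, and the other had 3.05 and 3.10 RPKM. The highest ratio was that of Contig9972, 32.2-fold (26.0 to 40.3). The list of 27 (14 higher, 7 lower) had a relative median of 0.78 (percentile 99.9), but its summed level was 7532 RPKM in FE and 20270 in PE. The sign of its median turned with 1 unigene per protein (-0.36) and without receptors that matched the pattern (-0.38), so the list has no single direction.

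Cytochrome P450s, which oxidise lipids and xenobiotics, had 86 of 227 members lower in FE, 35 higher and 106 neither, with a relative median of -1.04 (-1.20 to -0.73) at percentile 0. With a TMM factor 113 were lower and 26 higher. Contig5750, the most abundant, had 353 RPKM in FE and 604 in PE. Contig34788 was 19.0-fold higher in PE (16.4 to 22.1), whereas Contig3336 was 173-fold higher in FE (96.6 to 348). KOG class Q, secondary metabolism, overlaps this list and had 121 of 369 unigenes lower and 76 higher (relative median -0.66), a result inside the random range with 1 unigene per protein (-0.14). Other detoxification genes, the sulfotransferases, esterases and ABC transporters, had 72 of 223 lower and 51 higher (-0.45, percentile 0), or 89 and 37 with a TMM factor. Their median was 0.01 with 1 unigene per protein. GO terms for such enzymes went opposite ways. Sulfotransferase activity (104 unigenes, 22 higher, 37 lower) had a relative median of -0.77, and cholinesterase activity (26 unigenes, 17 higher, 3 lower) had 1.04. A sulfotransferase (Contig1282) was 4.45-fold higher in PE (4.39 to 4.52) at 3893 RPKM, a salivary sulfotransferase (Contig51869) was 24.2-fold higher in PE (20.1 to 29.3), and another sulfotransferase (Contig1530) was 14.8-fold higher in FE (13.8 to 15.9). Glutathione S-transferases (34 members, 10 higher and 7 lower, or 9 and 12 with a TMM factor, -0.47) and antioxidant enzymes (33 members, 11 higher and 2 lower, or 9 and 5 with a TMM factor, 0.13) lay inside the random range.

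Solute transporters and aquaporins had 73 of 248 members lower and 62 higher, with a relative median of -0.34 (-0.61 to -0.07) at percentile 0 (90 lower and 45 higher with a TMM factor). The most abundant, an amino acid transporter (Contig4854), had 279 RPKM in FE and 306 in PE. A monocarboxylate transporter (Contig54190) was 19.3-fold higher in PE (14.2 to 26.8), and a transporter described as sodium-coupled monocarboxylate transporter 2-like (Contig690) was 13.1-fold higher in FE (10.8 to 16). As a further example, an aquaporin (Contig1001), a water channel, was 6.96-fold higher in FE (6.66 to 7.29). Vacuolar ATPase and endocytosis genes had 24 of 66 members higher and 3 lower, with a relative median of 0.28 at percentile 97.9, close to the edge of the random range. The small GTPase RAB-20 (Contig3427) was 7.96-fold higher in FE (7.62 to 8.32) and a Rab-1A-like unigene (Contig43729) 9.92-fold higher in PE (7.63 to 13.1), while the abundant Rab-1A-like Contig3823 had 173 and 217 RPKM. The endocytosis list was inside the random range under 6 of the alternatives.

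The peritrophic matrix is the chitin and protein layer that lines the gut around the blood meal. Of 68 unigenes with chitin, peritrophin or mucin descriptions, 26 were lower in FE and 21 higher, and the relative median of -0.20 lay inside the random range. With a filter at 5 RPKM it was -1.60, outside the range on the lower side, and without a filter 0.052, inside it. Of 10 unigenes described as peritrophic membrane chitin binding proteins 6 were lower in FE and 3 higher, with or without a TMM factor. Of these, 2 were among the 8 lowest ratios taken by the rule for named genes: Contig23449 had 6.97 RPKM in FE and 362 in PE, 52-fold higher in PE (47.0 to 57.6), and First_Contig2369 was 72.2-fold higher in PE (55.1 to 96.5). As further examples, a chitinase (Contig24007) was 30.0-fold higher in PE (26.3 to 34.5) and a secreted mucin (Contig544) 6.08-fold higher in FE (5.84 to 6.34).

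Lipid transport and lipolysis genes had 54 of 156 members higher and 31 lower, with a relative median of 0.22 at percentile 98.3, and 40 higher and 40 lower with a TMM factor. The list was inside the random range under 5 of the alternatives. Its pattern also matches acyl-CoA enzymes, among them fatty acyl-CoA elongases such as Contig23, which are neither lipid transport nor lipolysis. Values without these matches were not computed. A Niemann-Pick type C1 domain protein (Contig18507), of a family that moves sterols, was 11.7-fold higher in PE (11.3 to 12) at 1200 RPKM, although its UniProt hit names another protein. A lipase (Contig71006) was 37.6-fold higher in PE (25.4 to 58.4), and a phospholipase A2 precursor (Contig21775) was 98.6-fold higher in FE (64.3 to 160). Further examples were fatty acid elongases, which lengthen fatty acids. Of 21 unigenes 16 were higher in FE and 1 lower (11 and 2 with a TMM factor), led by Contig23 with 630 against 103 RPKM, 6.13-fold (5.89 to 6.38).

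Among 36 antimicrobial and immune unigenes 7 were higher in FE, 3 lower and 26 neither (6 higher and 6 lower with a TMM factor), and the list lay inside the random range (-0.14, percentile 25.2). The highest FE/PE ratio by the log2(RPKM + 1) measure among the unigenes ranked by the rule for named genes belonged to this list. It was a unigene described as salivary glands defensin (Contig307), a cationic antimicrobial peptide, with 5214 reads (419.5 RPKM) in FE and 3 reads (0.198 RPKM) in PE, a ratio of 2114 (723 to 10254). A peptidoglycan recognition protein (Contig41666), a sensor of bacterial cell walls, was 9.72-fold higher in PE (6.88 to 14.2).

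Of 6 histone unigenes 4 were higher in FE and none lower (3 and 0 with a TMM factor), with a relative median of 1.07 at percentile 99.0. Histone H2B (Contig1248) had 1623 RPKM in FE and 363 in PE, 4.47-fold (4.38 to 4.56), and histone H2A (Contig22446) was 5.49-fold higher (5.28 to 5.71). Another, Contig19794, was 2.30-fold higher (2.25 to 2.35), a call lost with a TMM factor, and it is 6671 nucleotides long and its UniProt hit is a Pol-like protein. DNA replication and cell cycle genes had 90 of 400 members higher, 23 lower and 287 neither (56 higher and 30 lower with a TMM factor). Their relative median was 0.19 at percentile 99.9, and 0.19 at percentile 94.3, inside the random range, with a filter at 5 RPKM. The pattern also matched 290 RNA-directed DNA polymerases of mobile elements, among them Contig10308, 21.5-fold higher in PE (19.9 to 23.4). Without them, in an alternative added after seeing the data, 50 of 110 were higher and 4 lower, with a relative median of 0.61 (0.39 to 0.74). The most abundant member, the replication factor SET (Contig96), had 285 and 272 RPKM. A unigene described as a topoisomerase-interacting protein BTBD1 (Contig12025) was 287-fold higher in FE (189 to 458). It matched only by the word topoisomerase, its KOG class is function unknown, and it stayed among the 110. As further examples, cyclin A (Contig5191), which drives S phase and mitosis, was 4.14-fold higher (3.90 to 4.40) and geminin (Contig2374), which limits replication licensing, 5.66-fold higher (5.32 to 6.02). Other annotations of replication and the cell cycle, chosen after their values were seen, were mixed in relative median. KOG class D, cell cycle control, lay inside the random range (0.05, percentile 77.0). So did the GO terms cell cycle (0.30), cell division (0.44) and DNA replication (0.04). The last had 14 higher and 3 lower, or 4 and 7 with a TMM factor. Above the range lay KOG class L (0.28) and the GO term regulation of cyclin-dependent kinases (1.00).

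By KOG class, 10 of 24 classes lay outside the random range, 9 of them above it. Transcription, class K, had the largest relative median, 0.73 (0.68 to 0.83), with 729 of 1351 unigenes higher in FE and 19 lower. The other classes above the range were RNA processing (0.08), amino acid metabolism (0.23), replication and repair (0.28), protein turnover (0.10), inorganic ion transport (0.16), general function (0.14), unknown function (0.26) and signal transduction (0.11). Several of these did not hold. With a filter at 5 RPKM amino acid metabolism lay outside the range on the lower side (-0.22), and protein turnover, RNA processing, ion transport and signal transduction fell inside it. RNA processing was inside it under 3 alternatives and ion transport under 5.

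**Figure D3:**
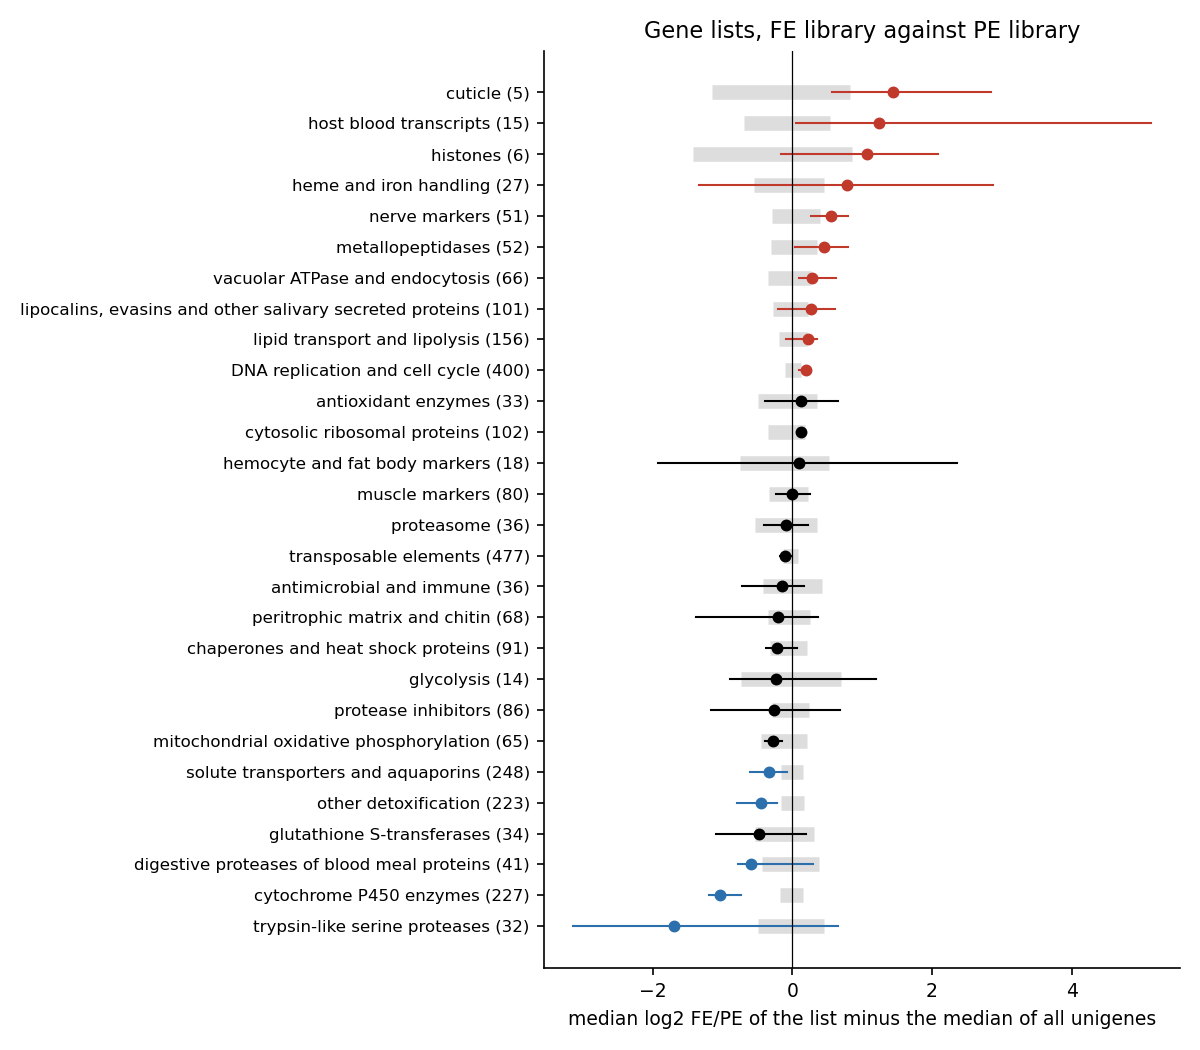
Median log2 FE/PE ratio of each of 28 gene lists minus the median of all unigenes (x axis, log2), with the number of unigenes in parentheses. Points and lines are medians and 95% intervals over members, grey bars the central 95% of 10000 random lists matched on level, and colour marks the 10 lists above (red) and 5 below (blue) that range, from -1.69 for trypsin-like serine proteases to 1.44 for cuticle.

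Among genes that every cell uses, cytosolic ribosomal proteins had 88 of 102 members called neither (relative median 0.12), oxidative phosphorylation 55 of 65 (-0.28), the proteasome 31 of 36 (-0.09) and chaperones 68 of 91 (-0.22), against 28439 of 44982 for all unigenes. Glycolysis had 9 of 14 (-0.24), about the share of all unigenes. These 5 lists lay inside the random range. The ribosomal proteins lay outside it with a pseudocount of 5 (0.26) and with a filter at 5 RPKM (0.034). Transposable elements had 85 of 477 unigenes higher and 35 lower (46 and 51 with a TMM factor), also inside it (-0.11) unless random lists were matched on length.

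A dissected gut can carry other tissues, and markers of these were listed separately. Muscle markers had 63 of 80 members within 2-fold and a relative median of -0.01 (-0.23 to 0.25). Nerve markers had 23 of 51 higher and 0 lower (0.55, 0.27 to 0.80, percentile 99.9), or 16 higher and 3 lower with a TMM factor, and lay inside the random range with a filter at 5 RPKM (0.25, percentile 84.3). A GABA transporter (Contig298) was 10.4-fold higher in FE (9.64 to 11.3), while synaptobrevin (Contig1012) had 119 and 85.8 RPKM and extended synaptotagmin-2 (Contig13626) 10.5 and 17.5. The 5 cuticle unigenes had a relative median of 1.44 at low levels, the most abundant (Contig37646) at 8.42 RPKM in FE and 1 read in PE. Salivary secreted proteins had 40 of 101 members higher and 28 lower, or 33 and 30 with a TMM factor. Their relative median of 0.26 (percentile 98.8) turned to -0.16 with a filter at 5 RPKM, and their summed level was 6449 RPKM in FE against 20298 in PE. The defensin Contig307 above is also in this list and had its highest ratio among members of at least 10 RPKM. A secreted salivary gland peptide (Contig15831) had 1060 and 825 RPKM, and another (Contig77870) had 2 reads in FE and 3935 in PE, a ratio of 1618 in favour of PE (447 to 13361). Hemocyte and fat body markers (18 members, 7 higher, 7 lower, 0.10) consisted mostly of the hemelipoglycoproteins above. Their relative median lay outside the random range at -1.41 with a filter at 5 RPKM, -0.68 with UniProt and 0.59 with Nr alone, so this list has no single direction either.

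The list meant for host blood transcripts held 15 unigenes, 11 higher in FE and 1 lower, with a relative median of 1.24 (percentile 99.98). Its pattern matched 9 immunoglobulin-binding proteins, whose Nr hits are proteins of the tick Ixodes scapularis, so the list cannot be read as host RNA. Without 11 false matches, removed after seeing the data, 4 unigenes were left, 3 higher in FE and 0 lower (median log2 ratio 1.04), too few for a percentile. Of the 9 immunoglobulin-binding proteins, 8 were higher in FE and 1 lower. Contig2378 had 8429 reads (341 RPKM) in FE and 2 reads in PE, a ratio of 5126 (1419 to 42337), and Contig60105 was 57.7-fold higher in PE (35.4 to 101).

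Other unigenes at the extremes were of varied kinds. Higher in FE were an L-asparaginase-like enzyme (Contig6538), 60.7-fold (50.9 to 73.0), an elongase of very long chain fatty acids (Contig7039), with 831 reads in FE and 0 in PE and so at least 337-fold higher, and 2 longipain unigenes, a papain-type protease of the tick midgut, at least 214-fold (Contig8241) and at least 210-fold (Contig8240) higher. Lower in FE was a deoxyribonuclease II (First_Contig2428), an acid nuclease, which was 131-fold higher in PE (104 to 165). A unigene described as barrier to autointegration factor (First_Contig299), a DNA-binding protein, was 67.3-fold higher in PE (62.0 to 73.1) at 1749 RPKM. That description rests on a Drosophila melanogaster hit, with no UniProt description and no KOG class. Also higher in PE were fatty-acid amide hydrolase 2-A (Contig17610), 43.6-fold (41.5 to 45.8), and a unigene described as putative papa 1 (Contig13525), 47.0-fold (40.5 to 54.7).

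**Figure D4:**
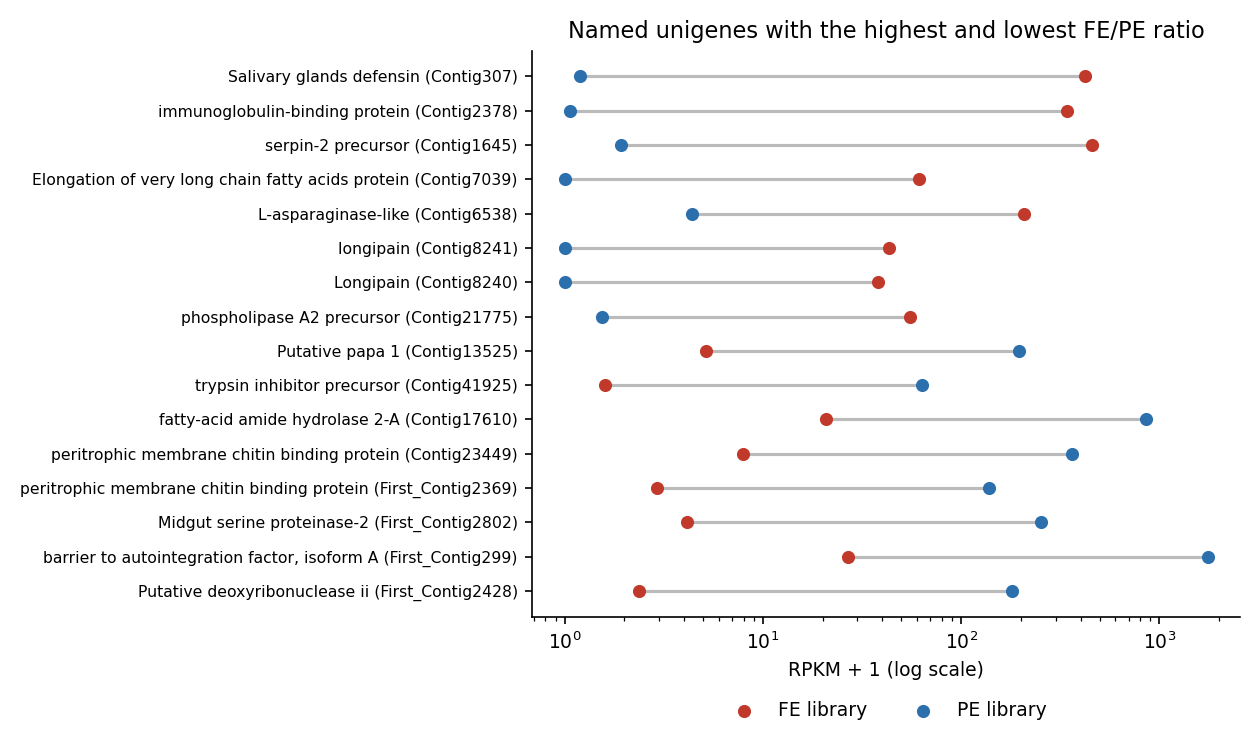
RPKM + 1 on a log x axis in the FE library (red) and the PE library (blue) for the 8 unigenes with the highest and the 8 with the lowest FE/PE ratio among those with an informative description and at least 10 RPKM in a library. Only the unigene with the highest mean level was kept per description, so more extreme unigenes that share one, such as Contig77870, are not shown. Salivary glands defensin is at the top (419.5 RPKM in FE, 0.198 in PE) and deoxyribonuclease II at the bottom (1.37 in FE, 179 in PE).

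Of the 10 described unigenes with the highest mean level over both libraries, 5 were neither higher nor lower, 4 were lower in FE and 1 was higher. With a TMM factor 5 were neither, 5 were lower, Contig757 being added, and none was higher. The 4 lower ones are the Kunitz inhibitor, chymotrypsin-C, Contig1058 and sulfotransferase Contig1282 given above. A unigene described as U1 small nuclear ribonucleoprotein A (Contig3003) had 12748 RPKM in FE and 13752 in PE, ribosomal protein S27 (Contig1744) 10348 and 8428, cytochrome c oxidase subunit I (Contig60) 5395 and 7679, and a neutrophil elastase inhibitor (Contig58) 4882 and 4059. BmSEI-like 1 (Contig28) was 2.01-fold higher in FE (1.99 to 2.03), a call lost with a TMM factor (log2 ratio 0.61). The 10 most abundant unigenes took 8.03% of the summed RPKM in FE and 10.7% in PE. The 10 unigenes with the most reads, ranked anew, took 8.99% of the implied library total in FE (95% interval 8.98 to 9.0%, exact Clopper-Pearson). In PE the share was 11.5% (11.49 to 11.51%).

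By the authors' deposited table, a total of 5228 unigenes had a false discovery rate under 0.05, of which 3771 were higher in FE and 1457 higher in PE. The rule of size called 3367 of the former higher and 1329 of the latter lower, and 0 in the opposite direction. Most of the 11551 higher and 4992 lower calls of the rule did not have a false discovery rate under 0.05 in that table. As the libraries are single, the authors' deposited values compare these 2 libraries and not the states of feeding.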

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

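With 1 library per state no replicate could be left out, and no paired analysis was possible because each group holds a single library. Of the 28 lists, 15 lay outside the random range, and 4 of these did so on the same side under every alternative fixed beforehand: trypsin-like serine proteases, cytochrome P450s, solute transporters and histones. Cuticle did so under 8 of 10, and with a filter at 5 RPKM or a TMM factor fewer than 5 members were left and it had no value. Over all lists and alternatives 245 of 283 values kept their side of the range. Of 48 named unigenes called by the rule, 46 kept their call with a TMM factor, all but Contig28 and Contig19794, while Contig757, Contig5750, Contig7836 and Contig13626, called neither, had log2 ratios below -1. Dropping the counting interval left the gene counts as they were. So did dropping the filter, since with a pseudocount of 1 no unigene under 1 RPKM can pass. Except where said, the cause of a change was not tested.

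Genes higher and lower in FE numbered 4743 and 2057 with a pseudocount of 5, 7437 and 3103 with a filter at 5 RPKM (fewer unigenes enter) and 2995 and 1452 with a 4-fold rule. With 1 unigene per protein 8 lists lay outside the range. The 10 unigenes with the most reads took 8.99% (FE) and 11.5% (PE) of the implied totals. Among unigenes with a Nr hit the 10 most abundant took 8.61% and 14% of the RPKM.

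The following relative medians crossed the edge of the random range. Changes of sign inside it, such as those of protease inhibitors (0.16), immune genes (0.054) and peritrophic matrix (0.052) without a filter, are otherwise not listed. With a filter at 5 RPKM they were 0.19 for replication, 0.13 for lipid transport, 0.25 for nerve and 0.15 for endocytosis (now inside), -1.11 for protease inhibitors, -1.60 for peritrophic matrix, -1.41 for hemocyte and fat body and 0.034 for ribosomal proteins (now outside), and of the other sign for salivary proteins (-0.16), metallopeptidases (-0.15), KOG class E (-0.22, outside on the lower side) and KOG class O (-0.030). Without a filter digestive proteases (-0.13), salivary proteins (0.23) and endocytosis (0.38) fell inside. With 1 unigene per protein KOG class Q (-0.14), digestive proteases (-0.44), host blood (0.74), lipid transport (0.21), metallopeptidases (0.30) and endocytosis (0.30) fell inside, and heme and iron (-0.36) and other detoxification (0.013) changed sign. Lipid transport (0.21) and salivary proteins (0.22) fell inside with a pseudocount of 0.1, lipid transport (0.082) with 5, and endocytosis with lists matched on length (0.28) or Nr alone (0.23). Ribosomal proteins with a pseudocount of 5 (0.26), transposable elements with lists matched on length (-0.11) and hemocyte and fat body with Nr alone (0.59) fell outside. With UniProt alone heme and iron (0.36), host blood (0.68), lipid transport (0.11), metallopeptidases (0.33) and endocytosis (0.11) fell inside and protease inhibitors (-0.34) and hemocyte and fat body (-0.68) outside. Without false matches, added after seeing the data, protease inhibitors (-0.34) and hemocyte and fat body (-0.85) lay outside, heme and iron changed sign (-0.38), and host blood kept 4 members, 3 higher and 0 lower, and had no percentile.

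Among the other KOG classes, A fell inside with a pseudocount of 0.1 (0.066), with a filter at 5 RPKM (0.010) and with lists matched on length (0.081). Class P did so with a pseudocount of 5 (0.084), the same filter (0.013), centring (0.13), a TMM factor (0.13) and length matching (0.16), and class T with the filter (0.012). The filter put B (0.16), D (0.16), F (-0.39) and G (-0.29) outside. So did 1 unigene per protein for D (0.22) and U (0.13), and a pseudocount of 5 for J (0.18) and U (0.14). Class U was also outside with centring (0.09) and with a TMM factor (0.09).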

Other observations

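The tests in this part were chosen after the results were seen, except that of redundant fragments for the zinc finger unigenes, whose outcome had not been seen, and the GO terms and families below were also picked after their values were known. GO terms with at least 20 unigenes numbered 262, of which 80 lay outside the central 95% of 2000 random lists matched on level. By chance 5% or 13.1 would, if the unigenes within a term were independent, which fragments of 1 gene are not. Terms also share unigenes, so the 80 are not separate results. Fucosyltransferase activity, the transfer of fucose to glycans, had the highest relative median of the molecular functions, 1.36, with 30 of 37 unigenes higher in FE and 2 lower (27 and 2 with a TMM factor). An alpha 1,3-fucosyltransferase (Contig5505) had 150 RPKM in FE and 10.1 in PE. Regulation of cyclin-dependent kinases (23 unigenes, 14 higher, 1 lower, 1.00) and cholinesterase activity (26 unigenes, 17 higher, 3 lower, 1.04) were also above the range, although the most abundant acetylcholinesterase (Contig318) had 38.2 and 43.9 RPKM. The lowest relative median was that of lipid transporter activity, -1.39 (35 unigenes, 9 higher, 18 lower), a term that holds the abundant hemelipoglycoproteins.

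Protease inhibitors and peritrophic matrix genes had more lower than higher calls in FE among abundant members, and the reverse among scarce ones. All unigenes went the same way, and a difference from them was not tested. Of all unigenes with a mean of at least 100 RPKM 160 of 1018 were higher and 285 lower. Among those below 10 RPKM the numbers were 7931 of 33028 and 3381. The listed protease inhibitors, without Contig58, had 3 higher and 11 lower of 15 at or above 100 RPKM, and 20 higher and 6 lower of 42 below 10 RPKM. Peritrophic matrix genes had 3 higher and 9 lower of 13, and 14 higher and 4 lower of 35. Amidases included First_Contig665, with 52.8 RPKM in FE and 1863 in PE, yet 10 of 23 were higher and 9 lower (10 and 10 with a TMM factor). All 4 transferrin receptor unigenes were higher in FE, at no more than 13.2 RPKM. Among the 100 most abundant unigenes 22 in FE and 23 in PE had no protein description, and 1 of these, First_Contig73, had 1061 RPKM in FE and 10632 in PE.

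More unigenes were higher in FE than lower. Depth differed between the libraries. Thinning the PE reads to the FE total left 11561 higher and 4991 lower, a ratio of 2.32, but RPKM already divides by the totals and the counts hardly moved, so this decides nothing about depth. A TMM factor brought the ratio to 1.15, under a limit of 1.2 that was itself set after this value was seen. TMM centres the ratios on the assumption that most unigenes do not differ, which brings an even split by itself. Depth, scaling by read totals and a real difference in many transcripts therefore cannot be told apart here.

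Unigenes whose best KOG hit is a C2H2 zinc finger protein, a class of DNA-binding proteins, numbered 800, of which 690 were among the 1351 unigenes of KOG class K. Of the 800, 603 were higher in FE and 3 lower. Their median log2 ratio of 1.72 (1.65 to 1.8) lay above the 0.30 to 0.45 of random lists matched on level and length, and was 1.43 (1.35 to 1.52) with a TMM factor and 1.41 (1.21 to 1.66) over the 256 left with 1 unigene per best-hit protein. These values argue against level, length, scaling and fragments that share a best-hit protein as the whole source. Fragments of 1 gene that hit different proteins were not merged, so redundancy of that kind stays open. The rest of class K had a median log2 ratio of 0.57, against 1.09 for the whole class and 0.36 for all unigenes. These 3 values are not relative medians. Reads shared between similar zinc finger copies, variation between ticks, and the state of feeding stay open and were not tested.

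Markers of nerve and cuticle were higher in FE, the nerve list with 16 higher and 3 lower under a TMM factor and inside the random range with a filter at 5 RPKM. A lower share of midgut cells would raise all other tissues alike, whereas the medians of nerve and muscle markers differed by 0.56 (bootstrap 95% interval 0.15 to 0.92). Over the 27 nerve and 59 muscle unigenes of at least 5 RPKM the difference was 0.37 (-0.092 to 1.19), so this explanation cannot be told apart from a change in the gut. Ovary carried into the FE dissection might raise the vitellogenin receptor, the yolk receptor of the ovary. The 2 unigenes with this Nr description had log2 ratios of 1.57 (First_Contig2458) and 0.93 (Contig5844). The UniProt hit of Contig5844 is a putative low-density lipoprotein receptor. As the midgut level of the vitellogenin receptor is also unknown here, ovary and a change in the gut cannot be told apart. The feeding state itself remains an untested explanation.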
